A study of Mus musculus with 8 samples.

How the data were processed

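Single-cell RNA sequencing was done on the testes of 4 adult mice aged 10 weeks, 2 wild type and 2 homozygous for a mutant allele of Tex14 (Tex14 m/m). The labels pair the animals: each of the 2 pairs holds 1 wild-type and 1 mutant mouse, whose cells carried different multiplexing tags (lipid-anchored oligonucleotides) and were pooled in equal numbers before encapsulation in 2 droplet wells, with 6000 cells aimed at per mouse and well. The 2 wells of a pair are technical duplicates of one pool. The replicate is therefore the animal, with 2 against 2, and all 4 came from a single litter per the labels.

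The deposited matrices hold raw UMI counts per feature and barcode for every barcode of a well, per the file headers. The authors used Cell Ranger 7.0.1 and the mm10 genome, per the submitters' processing notes. The features are 32285 genes with Ensembl identifiers, 1237 transposon and other repeat names, and the tags. How reads were given to repeat features, and whether a read could count for a gene and a repeat at once, is not given in the sources used here. The deposited tag tables list each barcode called as a cell with the fraction from 0 to 1 that is the probability of each tag, of a multiplet and of a blank. Calls were taken as deposited, and the lowest probability of a called tag was 0.900. The called cells held 61576660, 59242857, 52768451 and 61107183 UMIs per well, which was 65.8 to 69.3% of the UMIs of a well.

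Cells with a tag call were kept at a minimum of 1000 UMIs and 500 genes and a maximum of 20% mitochondrial UMIs. Counts were scaled to 10000 per cell and log-transformed, and 3000 variable genes, 40 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 27 clusters (scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, python 3.11.15). X-linked, Y-linked, mitochondrial and repeat features were left out of the clustering, a choice made after seeing a cluster of mutant cells set apart by X-linked genes. Clusters were named from fixed marker genes, with at least 3 markers detected in 10% of the cluster's cells. No cluster stayed unnamed. A class was tested where each animal had at least 20 cells, which left out elongating spermatids, endothelial cells and lymphoid cells. The remaining 10 classes include the spermatogonia as a whole and their undifferentiated and differentiating parts.

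Cells called as tag multiplets were left out, and no further doublets were removed in the results given first. Scrublet (through scanpy, expected rate 0.06) called 3.26, 2.24 and 1.11% of the cells in 3 wells and 0.0653% of 7659 in the second well of pair 2, where it did not work; it marked 30.1, 35.5, 21.4 and 0% of the cells the tags called multiplets. For this reason cells above the 94th percentile of the score in each well were removed as another alternative.

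Raw counts were summed per animal and class over both wells and tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, glmQLFit and glmQLFTest, without a block), with Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are mutant over wild type with the standard error of the fit. Gene lists and marker lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with the adjustment over lists and classes. P-values with the correlation estimated from the data are given beside the calls, but have little power with 4 animals. For each list the number of members past the edgeR test over all genes is given beside the number adjusted over the list alone. Repeat features were tested beside the genes with the genes' scaling, a test chosen after seeing the data. DESeq2 1.42.0 was the other tool. The genes, lists, markers, tests and most alternatives were fixed before the data were examined.

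The named genes follow a fixed rule. It takes Tex14 in each class, then, among genes past the test with the same sign in both pairs and a mean of at least 50 CPM in 1 genotype, the 7 largest rises and the 7 largest falls, without genes named only by a Gm number, a Rik clone or an accession and without pseudogenes, then up to 4 members with the smallest p from each list with a call in the class. Where no gene passed, the 3 smallest p are given as not passing.

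The wells were shared within a pair, so the pair was checked as a block: deviations from the genotype means correlated between the 2 animals of a pair, with coefficients of 0.146 to 0.520 over the 10 classes. The pairing comes from the labels. The value with the pair as a block is given where it changes a call or a count by over 1.5 times. Single values per animal were compared with an exact two-sided permutation test, whose smallest p with 2 against 2 animals is 0.333, so no such comparison can pass 0.05. Exact binomial intervals at 95% and the limit of 3 counts set by a count of 0 cover counting error only.

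For the relation of X-linked and Y-linked transcripts across round spermatids, each cell was thinned to 2000 UMIs, cells below that were left out, the means of the clusters were removed, and Pearson correlations across cells were taken per animal, with the 171 pairs of autosomes as background. For the second measure, X-linked genes were split at random into 2 sets in 20 seeded draws and the shares of the sets were correlated. Chromosomes and coordinates came from the GENCODE annotation, mouse release 21 on mm10, which held 32235 of the 32285 genes, 1084 of them X-linked and 725 Y-linked.

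The tests were tried on simulated data before use. Of 100 genes changed 4-fold in a simulated class, 80 were recovered for spermatogonia, 85 for preleptotene to zygotene spermatocytes, 79 for pachytene to diplotene spermatocytes, 84 for round spermatids, 72 for Sertoli cells, 84 for Leydig cells, 23 for mesenchymal cells and 73 for macrophages. At 2-fold the numbers were 25, 28, 17, 10, 7, 9, 1 and 7 in the same order, with at most 10 false calls in a class and no wrong direction.

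The alternatives were DESeq2 and its size factors, no filter on low counts, the pair as a block, each animal left out, each well alone, subtraction of ambient RNA, Scrublet removal, stricter or looser filters, a tag probability of at least 0.99, clusters from wild-type cells alone and other resolutions. Chosen after seeing the data were clusters with sex-linked genes, removal of the highest Scrublet scores, single clusters, cells matched on UMIs and removal of cells rich in protamine UMIs. Ambient RNA was taken from barcodes under 100 UMIs and, except in spermatids, scaled to the protamine and transition protein UMIs of an animal's class, which this subtraction thereby takes to be free RNA.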

Results

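The transcriptomes of single testis cells were compared between mice homozygous for a mutant allele of Tex14 and wild-type mice, in a study whose title names the intercellular bridges of male germ cells. TEX14 is a component of the stable bridges that join the descendants of one spermatogonium. The bridges themselves were not measured here. Droplet libraries were made from 4 mice, 2 per genotype, and each wild-type mouse was pooled with 1 mutant mouse. Cell Ranger called 11593, 10941, 8105 and 10425 cells in the 4 wells. In wild-type mice 1 and 2 the tags assigned 5970 and 5917 cells, of which 4769 and 4177 passed the filters, with 44103920 and 38535339 UMIs. In mutant mice 1 and 2 the tags assigned 9187 and 6404 cells, of which 6115 and 4347 passed, with 41308113 and 41436330 UMIs. The median per cell was 5101 and 5695 UMIs in the wild types and 5332 and 6717 in the mutants. Mitochondrial transcripts took a median of 0.347 and 0.839% of the UMIs of a kept cell in wild types and 5.58 and 5.62% in mutants. Cell types were named from marker genes, so that each name below stands for cells like that type. The animal is the replicate throughout (n = 2 per genotype).

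Tex14 itself (ENSMUSG00000010342, mm10 chromosome 11, 87405065 to 87555823, plus strand) was detected at similar levels in both genotypes. In spermatogonia it stood at 185 and 158 CPM in wild types and 136 and 148 CPM in mutants, a log2 fold change of -0.27 ± 0.21 (SE). The change was -0.20 ± 0.20 in pachytene to diplotene spermatocytes and -0.68 ± 0.30 in round spermatids, neither past the edgeR test (adjusted p = 0.748 and 0.563). In preleptotene to zygotene spermatocytes it was 0.43 ± 0.22 (adjusted p = 0.167), which passed with the pair as a block (adjusted p = 0.00486). The mutant allele is not described in the sources used here and the libraries count 3' ends, so these values do not check the genotype.

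Germ cell development was shifted to its early stages in the mutants. Spermatogonia made up 5.50 ± 0.497% of the kept cells in wild types and 42.7 ± 0.998% in mutants (SD, n = 2 each), 7.77-fold more. Elongating spermatids, the last stage in the testis, were the largest class in wild types at 50.9 ± 9.51% and nearly missing in mutants at 0.258 ± 0.156%, with 9 cells in mutant 1 and 16 in mutant 2. Undifferentiated spermatogonia had shares of 0.629 and 0.503% in wild types and 5.10 and 5.13% in mutants, and differentiating spermatogonia 5.22 and 4.64% and 36.9 and 38.3%. Preleptotene to zygotene spermatocytes, in the first steps of meiosis, were at 3.61 and 2.49% in wild types and 7.93 and 17.9% in mutants.

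Later germ cells were less common. Pachytene to diplotene spermatocytes had shares of 13 and 21.2% in wild types and 4.01 and 8.10% in mutants. Round spermatids, the haploid cells after meiosis, had 13.8 and 19.2% in wild types and 4.40 and 13.6% in mutants. Somatic cells had larger shares in mutants: Sertoli cells, which nurse the germ cells, went from 2.10 and 1.22% to 13.7 and 6.05%, and Leydig cells, which make testosterone, from 0.986 and 2.51% to 17 and 5.04%. The shares of interstitial mesenchymal cells were 1.85 and 1.72% and 4.38 and 2.78%, and those of macrophages 0.923 and 1.51% and 5.40 and 2.05%. Lymphoid cells were at 0.105 and 0.192% in wild types and 0.589 and 0.276% in mutants, and endothelial cells at 0.168 and 0.622% against 0.409 and 0.437%. Both mutants lay on one side of both wild types in each class but the endothelial cells, with an exact two-sided permutation p of 0.333, the smallest that 2 against 2 animals allow, and 1 for endothelial cells. Cells were pooled in equal numbers per animal, so shares show no loss or gain in absolute numbers. The tags gave no call to 30.4, 32.3, 26.4 and 37.6% of the called cells of the 4 wells. Of these cells 607, 533, 137 and 456 had over 2% of their UMIs from protamine and transition protein genes, against 61, 65, 12 and 74 cells tagged as mutant, so the shares hold for tagged cells only.

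**Figure D1:**
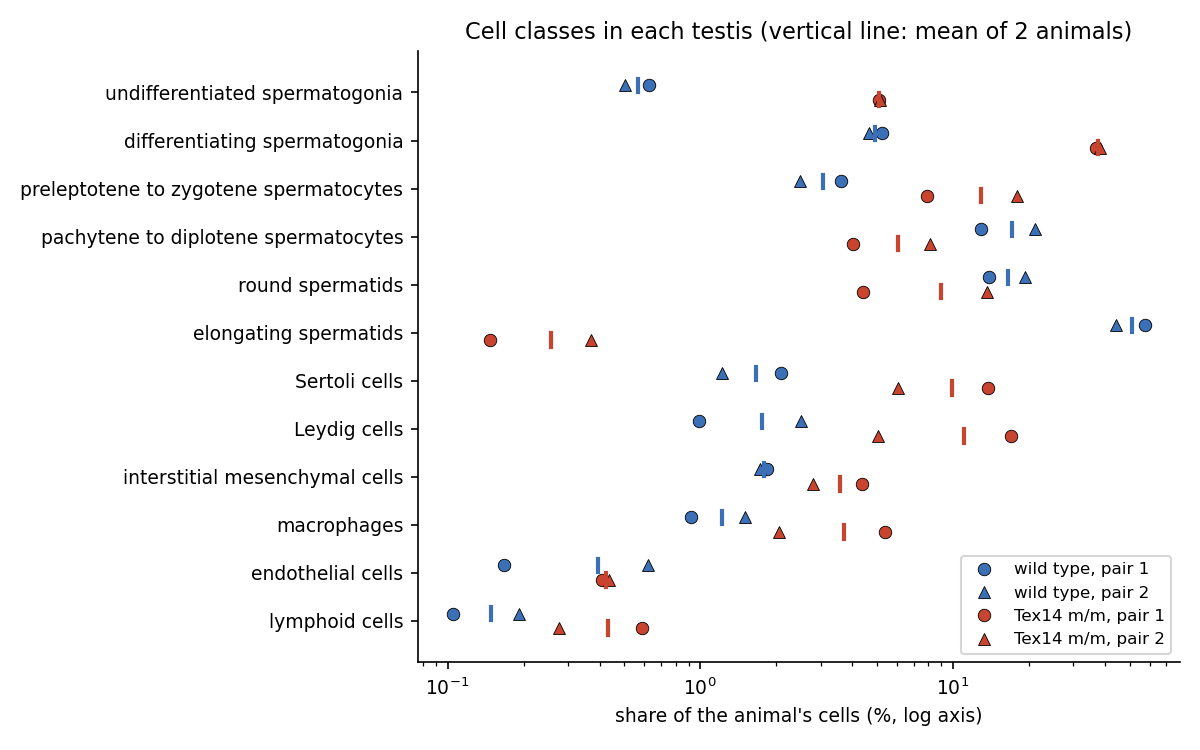
Share of each animal's kept cells (%, log axis) by cell class, with a point per animal (circles pair 1, triangles pair 2, blue wild type, red mutant) and a vertical line at the mean of a genotype. Elongating spermatids average 0.258% in mutants and 50.9% in wild types.

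Depth per cell differed between genotypes in some classes. Round spermatids had the most UMIs, with medians of 13109.5 and 10758 in wild types and 18801 and 18792 in mutants. Sertoli cells had 2162.5 and 1958 in wild types but 5570.5 and 8980 in mutants. Pachytene to diplotene spermatocytes ranged from 1882 in mutant 1 to 8115.5 in mutant 2, and differed less between the wild types, at 2330 and 3509.

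In spermatogonia, transcripts of late spermatids took a lower share of the UMIs in the mutants as groups, while genes of meiotic recombination and of spermatogonial self-renewal were higher as groups by small amounts. With an estimated correlation none of these calls held (adjusted p = 0.566 to 0.710). No single gene passed the edgeR test among 15020, with 180 higher and 196 lower at an unadjusted p under 0.05 and 1 gene called by DESeq2; with the pair as a block, 25 genes rose and 57 fell. The 3 smallest p, none passing, belonged to Npas3, a neuronal transcription factor gene, at a log2 fold change of 1.65 ± 0.30, to Tcea3, a transcription elongation factor gene, at -1.44 ± 0.29, and to Kcnd2, a potassium channel gene, at 1.32 ± 0.30. All of them passed with the block (adjusted p = 1.23e-05, 0.000103 and 5.7e-07).

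Of 34 sperm tail and motility genes, 32 were lower in mutant spermatogonia (median -0.50, camera adjusted p = 8.52e-10), among them Akap4, an anchor of protein kinase A in the fibrous sheath (-1.01 ± 0.31), and Odf2, an outer dense fibre gene (-0.54 ± 0.23). Of 25 acrosome and sperm head genes 22 were lower (median -0.48, adjusted p = 2.23e-06), of 15 genes of chromatin condensation 12 (-0.44, adjusted p = 8.39e-05) and of 21 genes of spermatid energy metabolism 16 (-0.34, adjusted p = 0.000704). The protamine genes Prm1 and Prm2, whose products pack sperm DNA, had -0.64 ± 0.26 and -0.83 ± 0.31, and Ldhc, the germ cell lactate dehydrogenase, -0.53 ± 0.25. The 13 elongating spermatid markers moved with them, all lower (median -0.69, adjusted p = 7.4e-15), as did the 17 round spermatid markers (-0.52, adjusted p = 8.87e-07). Of the 34 genes of meiotic double-strand breaks and recombination 30 were higher (median 0.16, adjusted p = 0.00169), such as Shoc1, needed for crossovers, at 0.86 ± 0.34. Of the 15 self-renewal genes 13 were higher (median 0.29, adjusted p = 0.00126), such as Itga6, an integrin of stem cells, at 0.60 ± 0.26 and Utf1 at 1.19 ± 0.56. No member of these lists passed singly, over all genes or adjusted over the list alone. The 20 genes of intercellular bridges and cytokinesis had a median of -0.04 (adjusted p = 0.631) and the 33 of the piRNA pathway 0.04 (adjusted p = 0.159). The synaptonemal complex list had 0.12 (adjusted p = 0.0537) and passed with the block (adjusted p = 0.00932), and so did the undifferentiated spermatogonia markers (0.16, adjusted p = 0.059, with the block 0.0264). Leaving out 1 animal ended the calls of acrosome genes (median -0.19), energy metabolism (-0.03) and recombination (0.06) without mutant 2, of chromatin condensation without wild type 2 (-0.16) and of self-renewal without wild type 1 or mutant 2 (0.36 and 0.27). Without mutant 1 the acrosome median was -1.07. With ambient RNA subtracted the acrosome and energy metabolism medians turned to 0.43 and 0.16. Over the genes of the 4 spermatid lists together (95, median -0.46) the median was -0.17 with cells matched on UMIs and -0.044 with ambient RNA subtracted.

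Undifferentiated spermatogonia alone had the 10 measured genes of meiotic initiation higher (median 0.61, camera adjusted p = 0.000101), including Stra8, the retinoic acid-induced gate to meiosis, at 49.2 and 111 CPM in wild types and 191 and 162 in mutants (1.19 ± 0.37), and Meioc (2.13 ± 0.79). No list call in these cells held with an estimated correlation (adjusted p = 0.598 to 0.734). Of 37 DNA replication genes 28 were higher (median 0.26, adjusted p = 0.00715), such as Pcna, the replication clamp (0.60 ± 0.32), and of 16 synaptonemal complex and cohesin genes 13 (0.25, adjusted p = 0.0134), such as Smc1b, a meiotic cohesin (0.79 ± 0.35). The spermatid lists were lower, with medians of -0.71 for the tail, -0.52 for chromatin condensation, -0.49 for the acrosome and -0.25 for energy metabolism (adjusted p = 6.69e-06, 2.88e-05, 0.0197 and 0.0108). No gene passed alone among 10304 (edgeR, 154 higher and 205 lower at an unadjusted p under 0.05, 0 by DESeq2, 1 down with the block), and adjusted over the list alone 3 chromatin condensation genes fell and no other member of these lists passed. The smallest p belonged to Crisp2 (-1.71 ± 0.33), Smcp (-1.38 ± 0.29), both sperm genes, and Kcnd2 (3.03 ± 0.68). Without cells rich in protamine UMIs, a setting that removed 1 cell of wild type 2 and 1 of mutant 1, the calls of chromatin condensation and energy metabolism ended (-0.13 and -0.068). Leaving out 1 animal ended the calls of meiotic initiation (without wild type 1, 0.37), DNA replication (without wild type 2 or mutant 1, 0.31 and 0.11), the synaptonemal complex (without wild type 1, wild type 2 or mutant 1, 0.31, 0.21 and 0.21). It also ended those of the acrosome (without wild type 1, 0.60, and without mutant 2, 0.10), chromatin condensation (without wild type 2, -0.22) and energy metabolism (without wild type 1 and mutant 2, -0.18 and -0.26). With ambient RNA subtracted the energy metabolism median was 0.043. Singly, 18, 5, 3 and 4 genes passed without wild type 1, wild type 2, mutant 1 and mutant 2.

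In differentiating spermatogonia no gene passed among 14304 (178 higher and 192 lower at an unadjusted p under 0.05, 1 by DESeq2, 10 up and 9 down with the block). Npas3 had 1.60 ± 0.32, Tcea3 -1.43 ± 0.29 and Pdzrn3 1.31 ± 0.30, which passed with the block (adjusted p = 0.0138, 0.0103 and 0.0138). The lists stood as in all spermatogonia, with medians of 0.16 for recombination, -0.48 for the tail, -0.45 for the acrosome, -0.43 for chromatin condensation and -0.35 for energy metabolism (camera adjusted p = 0.00105, 1.01e-08, 2.23e-06, 0.000375 and 0.00189; adjusted p = 0.598 to 0.645 with an estimated correlation). In 7 of 7 inflammation and tissue remodelling genes the value was higher (median 0.26, adjusted p = 0.0332, 0.0636 with the block), led by Spp1, the osteopontin gene, at 2.25 ± 0.79. This last call ended without wild type 1, wild type 2 or mutant 2 (medians 0.40, 0.41 and 0.19). Without mutant 2 the calls of recombination, acrosome and energy metabolism ended as well (0.05, -0.19 and -0.04) and 3 genes passed singly, and without wild type 2 that of chromatin condensation (-0.19). With ambient RNA subtracted the acrosome and energy medians were 0.45 and 0.15.

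Preleptotene to zygotene spermatocytes differed most by number of genes: 1597 rose and 1598 fell in the mutants among 9962 tested (edgeR, adjusted p = 0.000643 at the smallest). Genes of the X chromosome were higher nearly without exception, and genes that come on later in meiosis were lower. The glycosylphosphatidylinositol-anchored Gml fell from 874 and 710 CPM to 80.2 and 88.5 (-3.23 ± 0.24), and its neighbour Gml2 by 3.11 ± 0.25. Piwil1, the Argonaute protein MIWI that binds pachytene piRNAs, stood at 267 and 178 CPM in wild types and 30.7 and 25.5 in mutants, 8.02-fold lower (-3.00 ± 0.29). The wild-type cells lay mostly in cluster 4 (143 of 172 and 85 of 104 cells) and the mutant cells mostly in cluster 5 (378 of 485 and 603 of 776), so most of the comparison is between clusters.

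The other large falls were of Lypd11 (-3.44 ± 0.29), Gstt2, a glutathione transferase gene (-3.40 ± 0.37), Cers3, the ceramide synthase of very long chains (-3.39 ± 0.30), Elfn2 (-3.07 ± 0.37) and Prr7 (-3.07 ± 0.32). Rises were largest for Hist1h1e, a linker histone gene (2.97 ± 0.64), Pclo, which encodes a presynaptic scaffold (2.78 ± 0.35), Luzp4 (2.67 ± 0.39), Dock4, a guanine nucleotide exchange factor gene (2.65 ± 0.31), Cadps2 (2.56 ± 0.36), Jade3 (2.54 ± 0.40) and Aifm1, the apoptosis-inducing factor of mitochondria (2.54 ± 0.36). Luzp4, Jade3 and Aifm1 are X-linked. All 14 passed (adjusted p = 0.000643 to 0.00833). With 1 animal left out, 2132 to 2864 genes passed, and all 14 genes kept their call. At Leiden resolution 0.5 no gene passed, and Gml (0.28), Gml2 (0.24), Lypd11 (0.19), Gstt2 (0.19) and Cadps2 (-0.35) turned in direction. The value of Hist1h1e moved to 2.25 without wild type 1, 3.61 without wild type 2 and 2.01 without mutant 2, that of Luzp4 to 3.29 without wild type 1 and that of Gstt2 to -4.06 without mutant 2.

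Of 30 genes of the piRNA pathway and transposon repression, 14 fell and 2 rose in these spermatocytes (14 and 4 adjusted over the list alone, median -0.71, camera adjusted p = 0.000377). With an estimated correlation the lists called in these cells had an adjusted p = 0.598, or 0.833 for recombination, and the markers an adjusted p = 0.566 to 0.867. Beside Piwil1, Tdrd5, a Tudor protein gene of the germ granule (-3.01 ± 0.31), and Morc2b (-2.35 ± 0.29) fell, and Hells, a chromatin remodeller that helps DNA methylation, rose from 226 and 193 to 570 and 703 CPM (1.60 ± 0.24). Of 37 DNA replication genes 20 rose and 2 fell (22 and 2 over the list alone, median 1.08, adjusted p = 7.63e-06), among them Lig1 (1.71 ± 0.26), Pole (1.73 ± 0.28), Gins3 (1.97 ± 0.35) and the helicase subunit Mcm6 (1.45 ± 0.26). The 34 recombination genes went both ways, with 15 up and 7 down (16 and 8 over the list alone, median 0.50, adjusted p = 0.0334). The X-linked Tex11 (2.02 ± 0.24), the DNA damage kinase Atm (2.27 ± 0.31) and the PRDM9 partner Zcwpw1 (1.66 ± 0.24) rose, and the histone H2afx fell (-1.94 ± 0.26). Sperm tail genes had 12 falls among 29 (14 over the list alone, median -0.72, adjusted p = 0.000154), such as Spag16 (-2.72 ± 0.24), Spag17 (-2.06 ± 0.25) and Dnah1, an axonemal dynein (-2.37 ± 0.36). Energy metabolism had 9 among 20 (9 over the list alone, median -0.93, adjusted p = 5.61e-05), such as the testis cytochrome c gene Cyct (-2.71 ± 0.25), Cox6b2 (-2.59 ± 0.23) and Pdha2 (-2.28 ± 0.23). The neighbouring stages moved with these lists: 8 of 12 markers of differentiating spermatogonia rose (median 1.43, adjusted p = 0.00353) and 9 of 14 of pachytene to diplotene cells fell (median -1.15, adjusted p = 1.46e-07). Of 18 preleptotene to zygotene markers 9 rose and 2 fell (0.67, adjusted p = 0.0426). Synaptonemal complex, meiotic initiation, bridge and p53 lists were not called (medians 0.13, 0.37, 0.08 and 0.99, adjusted p = 0.619, 0.181, 0.848 and 0.248), and the CREM list was only with the block (-0.52, adjusted p = 0.084, with the block 0.0336). Recombination lost its call without wild type 1 or mutant 2 (0.53 and 0.46), and at Leiden resolution 0.5 the piRNA median was 0.05 and H2afx had 0.36.

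Within cluster 4 alone, a comparison chosen after seeing the data, 424 genes rose and 105 fell. Stra8 was higher in the mutants at 3.99 (adjusted p = 0.00137, with 5 and 4 UMIs in wild types and 35 and 65 in mutants). So were Prdm9, which places meiotic breaks, at 3.27 (adjusted p = 0.00791) and the Y-linked zinc finger genes Zfy1 and Zfy2 at 3.53 and 3.36 (adjusted p = 0.00341 and 0.00137). Piwil1 had -1.07 there and no longer passed (adjusted p = 0.0591).

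Repeat transcripts, tested beside the genes after seeing the data, changed in the same spermatocytes. MMERVK10C, an endogenous retrovirus of the ERVK group, rose by 1.21 ± 0.27 (edgeR adjusted p = 0.0309) and by 2.41 ± 0.33 within cluster 4 (adjusted p = 0.00172). Of 154 repeat features 6 rose and 4 fell. The other rises were RLTR10C (1.86 ± 0.26), IAPEy-int (2.52 ± 0.64), RLTR44-int (1.40 ± 0.36), ERVB4_1B-I_MM (1.27 ± 0.31) and the 5' part of a young LINE-1, L1MdTf_III_5end (1.35 ± 0.31). The falls were IAPLTR3-int (-3.43 ± 0.35), IAPLTR3 (-2.25 ± 0.43), RLTR13D1 (-2.61 ± 0.54) and LTRIS3 (-1.78 ± 0.35), with adjusted p = 0.000475 to 0.0496. Within cluster 4, 25 rose, among them L1MdF_V_5end (1.82), and IAPLTR3-int fell (-1.31). At Leiden resolution 0.5 no feature passed and IAPLTR3 had 0.42.

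In the remaining 9 classes no repeat feature passed. At an unadjusted p under 0.05 there were 3 up and 0 down in spermatogonia, 10 and 2 in pachytene to diplotene spermatocytes and 2 and 2 in round spermatids, 1 to 3 up and 0 to 7 down in the others, and with the block 2, 15 and 1 passed. The block also called 2 features in undifferentiated spermatogonia and 1 each in Sertoli cells and macrophages. Without wild type 1 there were 7 in Leydig cells, 3 each in undifferentiated spermatogonia and mesenchymal cells and 2 in Sertoli cells. MMERVK10C had 0.24 in spermatogonia, and it passed only with the block in pachytene to diplotene spermatocytes (0.66, adjusted p = 0.413, with the block 3.57e-09), round spermatids (0.67, adjusted p = 0.996, with the block 0.0219) and Sertoli cells (1.56 ± 0.37, adjusted p = 0.169, with the block 0.0172). Older LINE-1 elements were lower as a group in spermatogonia (median -0.28, camera adjusted p = 0.00522, adjusted p = 0.994 with an estimated correlation), and young LINE-1 elements in preleptotene to zygotene cells were not called (0.26, adjusted p = 0.711). Leaving out 1 animal ended the calls of MMERVK10C (without wild type 2, 0.90), IAPEy-int and L1MdTf_III_5end (without mutant 2, 1.42 and 0.87), RLTR44-int (without wild type 2 or mutant 2, 1.14 and 1.17), ERVB4_1B-I_MM (without wild type 1, wild type 2 or mutant 1, 1.45, 1.12 and 1.11). The same held for the RLTR13D1 repeat in preleptotene to zygotene spermatocytes (without wild type 1, -2.17) and LTRIS3 (without wild type 1, -1.46). Without mutant 2 RLTR13D1 had -3.34 and IAPLTR3-int -4.13. In total 23 and 20 features passed without wild type 2 and mutant 1. How reads were given to repeats is not stated in the sources used here.

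In pachytene to diplotene spermatocytes the genes of spermatid chromatin and of the Y chromosome were lower and the genes of earlier stages and of the p53 pathway higher, as groups. With an estimated correlation the adjusted p = 0.566 to 0.645 for the lists and markers called here and 0.112 for the Y-linked genes. No single gene passed edgeR among 14073, with 947 higher and 443 lower at an unadjusted p under 0.05; DESeq2 called 21 up and 21 down, and with the block 1432 rose and 1446 fell. Without mutant 2, the animal with the deeper cells of this class, 656 rose and 83 fell, without mutant 1 127 genes passed and without wild type 1 11. Of these cells 309 of 618 in wild type 1, 144 of 245 in mutant 1 and 202 of 352 in mutant 2 lay in cluster 13, while wild type 2 had 365 of 884 there and 444 in cluster 17, which held 211, 47 and 65 cells of the others. The antisense transcript Aknaos (-3.48 ± 0.44), the Fc receptor gene Fcgr3 (1.81 ± 0.30) and Stra8 (2.34 ± 0.39, 3.75 and 4.07 CPM in wild types, 26.8 and 14.1 in mutants) had the smallest p (adjusted p = 0.275, 0.408 and 0.408) and passed with the block (adjusted p = 1.26e-28, 1.79e-09 and 2.8e-13).

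Of 16 genes of chromatin condensation 13 were lower in these cells (median -0.70, camera adjusted p = 1.44e-07, 9 down adjusted over the list alone), such as the kinase gene Tssk6 (-1.43 ± 0.25), the spermatid histone H1fnt (-0.85 ± 0.23) and the Y-linked Ssty2 and Sly (-2.56 ± 0.69 and -1.77 ± 0.51). Of 21 energy metabolism genes 19 were lower (-0.24, adjusted p = 8.05e-05, 1 over the list alone), led by the sperm glycolytic enzyme gene Gapdhs at 114 and 113 CPM in wild types and 57.8 and 50.1 in mutants (-1.08 ± 0.20). The acrosome and tail lists were lower as well (-0.30 and -0.24, adjusted p = 0.000272 and 0.00102, none over the list alone). Of 15 p53 target and apoptosis genes 13 were higher (median 0.87, adjusted p = 0.000206, 3 over the list alone). Bax, which opens the mitochondrial membrane, had 10.8 and 6.92 CPM in wild types and 47.1 and 16.2 in mutants (1.81 ± 0.51), Btg2 1.90 ± 0.53 and Apaf1, the apoptosome scaffold, 2.12 ± 0.72. Recombination (median 0.55, adjusted p = 0.000154, 1 over the list alone), DNA replication (0.37, adjusted p = 0.000103), the piRNA pathway (0.22, adjusted p = 0.00637) and self-renewal (1.18, adjusted p = 0.00141) were higher. Their members included Dmc1 at 1.32 ± 0.35, Mcm3 at 2.3 ± 0.49, Hells at 1.44 ± 0.35, the ERV silencer Tex19.1 at 1.61 ± 0.40 and Zbtb16, the PLZF gene of stem cells, at 1.42 ± 0.61. Markers of differentiating spermatogonia moved with them (1.53, adjusted p = 1.51e-08), as did those of preleptotene to zygotene cells (0.43, adjusted p = 2.87e-05), and the elongating spermatid markers were lower (-0.95, adjusted p = 1.05e-17). Meiotic initiation was called only with the block (0.03, adjusted p = 0.084, with the block 0.0184). Calls ended for recombination without mutant 2 (0.15), for the piRNA pathway without wild type 1 or mutant 2 (0.14 and 0.12), for DNA replication and the tail without mutant 1 (0.24 and -0.16) and for the acrosome without wild type 1 or mutant 2 (-0.23 and -0.25). With clusters from wild-type cells alone the acrosome median was 0.04 and that of recombination 0.013, and with ambient RNA subtracted that of chromatin condensation 0.23.

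Round spermatids of the mutants, summed per animal, had higher X-linked and lower Y-linked transcripts, and p53 targets were higher as a group. With an estimated correlation the sex-linked calls had an adjusted p = 0.112 and the lists and markers called here an adjusted p = 0.566 to 0.781. The X share of the median cell was 0.934 and 0.959% in wild types but 1.05 and 0.213% in mutants. One gene passed edgeR among 15366: Gm13306 (ENSMUSG00000073877, chromosome 4), of a family with near-identical copies that may share reads, fell from 21.2 and 34.3 CPM to 0.825 and 0.313 (-5.77 ± 0.52, adjusted p = 0.0489). It lies outside the rule for named genes and was picked after its value was seen. DESeq2 called 50 up and 24 down, the block 538 up and 251 down, and 72, 142, 158 and 66 genes passed without wild type 1, wild type 2, mutant 1 and mutant 2. The X-linked Btbd35f27 (2.12 ± 0.31), the angiopoietin-like Angptl2 (4.55 ± 0.68) and Acot12, an acyl-CoA thioesterase gene (2.14 ± 0.32), did not pass (adjusted p = 0.2 each) and passed with the block (adjusted p = 6.31e-05, 0.00016 and 5.47e-05). Wild-type cells lay mainly in clusters 11, 15 and 18 and mutant cells in clusters 15 and 23.

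Of 15 p53 target genes 14 were higher in round spermatids (median 0.98, camera adjusted p = 7.63e-06, none over all genes or adjusted over the list alone), such as Btg2 (1.64 ± 0.46), Bax (0.98 ± 0.36) and Cdkn1a, the cell cycle inhibitor p21 (1.06 ± 0.41). Of 17 chromatin condensation genes 14 were lower (median -0.44, adjusted p = 3.37e-05, 1 up and 5 down over the list alone). Prm1 had 1213 and 1308 CPM in wild types and 710 and 483 in mutants (-1.08 ± 0.24). Ssty2 and Sly had -1.78 ± 0.31 and -1.47 ± 0.34, and the X-linked histone gene H2afb1 went the other way (1.65 ± 0.33). Recombination (0.38, adjusted p = 0.0363) and DNA replication (0.17, adjusted p = 0.0196, such as Mcm2 at 1.85 ± 0.66) were higher, and acrosome genes lower in 23 of 25 (-0.19, adjusted p = 0.0302, such as Acrv1 at -0.39 ± 0.21), with no member past the list alone. Markers of differentiating spermatogonia were higher with them (0.93, adjusted p = 1.24e-06), and those of round and elongating spermatids lower (-0.25 each, adjusted p = 0.011 and 4.98e-05). The tail and meiotic initiation lists passed only with the block (-0.13 and 0.30, adjusted p = 0.084 and 0.0859, with the block 0.0309 and 0.0427). Without the highest Scrublet scores the calls of chromatin condensation (-0.27), the acrosome (-0.14), DNA replication (0.076) and recombination (0.15) ended. Calls ended without wild type 1 for DNA replication, recombination and the acrosome (0.18, 0.12 and -0.11), without mutant 1 for DNA replication (0.21) and without mutant 2 for recombination and the acrosome (0.06 and -0.22). Within cluster 18 alone, chosen after seeing the data, 193 genes rose, 140 of them X-linked, and 10 fell.

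The sex chromosomes are silenced from pachytene on in male meiosis and remain largely repressed in round spermatids. In preleptotene to zygotene spermatocytes X-linked genes gave 0.700 and 0.676% of the UMIs in wild types and 2.38 and 2.44% in mutants, 3.50-fold more. Of 348 X-linked genes 261 rose and 0 fell (294 and 0 adjusted over the list alone, median 1.83, also with the gene at 0 in wild types at its bound, camera adjusted p = 2.35e-39). All 8 Y-linked genes rose (median 1.83, adjusted p = 3.82e-06). In cluster 4 the X share was 0.369 and 0.299% in wild types and 1.8 and 1.78% in mutants, and in cluster 5 it was 2.39 and 2.61% and 2.49 and 2.60%. In pachytene to diplotene cells the X share was 0.268 and 0.264% in wild types and 0.50 and 0.323% in mutants, with 85 of 393 genes lower (0.53, adjusted p = 3.27e-13) and none past the test. Of the Y-linked genes 22 of 29 were lower (-1.09, adjusted p = 1.27e-09, 4 over the list alone). Within cluster 17 the X median was -0.11, and at a tag probability of at least 0.99 the Y median was 0.42. The Y share of mutants was 0.845 and 1.06 times that of wild types within cluster 13 and 1.01 and 0.935 times within cluster 17. Round spermatids had 0.949 and 0.946% X-linked UMIs in wild types and 1.55 and 1.62% in mutants, while the Y share went from 0.0865 and 0.0916% to 0.0430 and 0.0380%. There 429 of 478 X-linked genes were higher (0.66, adjusted p = 6.27e-33, 51 over the list alone) and 59 of 61 Y-linked genes lower (-1.34, adjusted p = 1.79e-67, 53 over the list alone). In spermatogonia the X share was 2.00 and 1.90% against 2.00 and 2.07%. With an estimated correlation the adjusted p = 0.112 to 0.456 for these calls. X-linked genes were also called higher in Sertoli, Leydig and mesenchymal cells, by less (medians 0.17, 0.11 and 0.24, adjusted p = 0.0214, 0.0137 and 0.000713, and 0.456, 0.497 and 0.497 with an estimated correlation). These calls ended without mutant 2 (0.13, 0.089 and 0.026), without wild type 2 in Sertoli and Leydig cells (0.13 and 0.10), without wild type 1 in mesenchymal cells (0.14), without cells rich in protamine UMIs in Sertoli cells (0.12, and -0.074 with ambient RNA subtracted) and without the highest Scrublet scores (0.090, -0.024 and 0.078). Each difference in share had an exact permutation p of 0.333 in the meiotic and later classes (n = 2 per genotype).

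**Figure D2:**
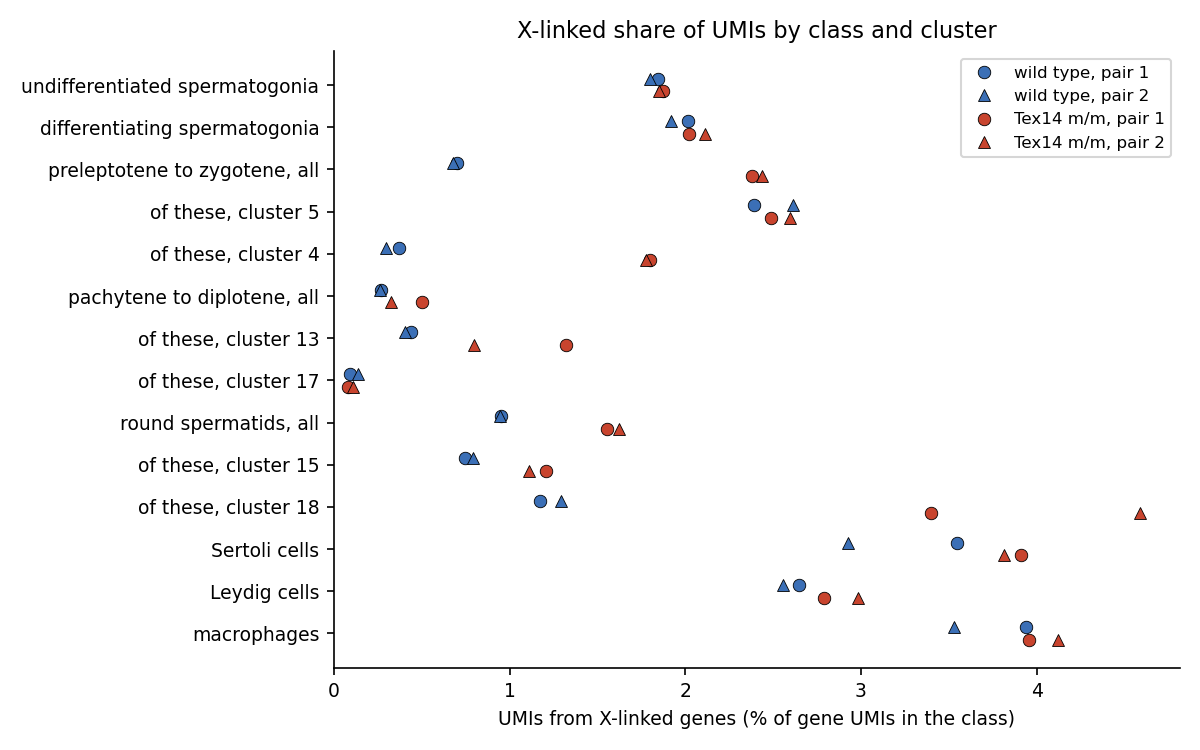
X-linked UMIs as a share of all gene UMIs (%) by class and, for the meiotic and haploid classes, by cluster, with a point per animal (circles pair 1, triangles pair 2, blue wild type, red mutant). Within cluster 5 the genotypes overlap.

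A round spermatid carries an X or a Y chromosome, and bridges let products of either reach both kinds of cell. Across round spermatids thinned to 2000 UMIs (588 and 688 wild-type and 240 and 560 mutant cells, with 72, 116, 29 and 31 shallower cells left out), the X and Y shares correlated with r = -0.0492 and 0.0428 in wild types and -0.332 and -0.357 in mutants. The means were -0.00321 ± 0.0650 and -0.345 ± 0.0172 (SD over animals, n = 2 each), and the difference of -0.341 had an exact permutation p of 0.333. Pairs of autosomes averaged -0.0399, -0.0355, -0.0126 and -0.0307. Random sets of X-linked genes correlated with each other across cells at 0.285 and 0.318 in wild types and 0.920 and 0.917 in mutants, where no autosome exceeded 0.220 and 0.157. In wild types chromosome 16 exceeded the X chromosome, at 0.367 and 0.426. Unthinned, the X to Y correlations were 0.0222 and 0.0659 in wild types and -0.384 and -0.494 in mutants. Cells are not independent replicates, so each correlation describes 1 animal.

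Single mutant round spermatids varied widely in X share, taken over all UMIs of cells with at least 2000. Under 0.3% of UMIs were X-linked in 1 of 588 and 2 of 688 wild-type cells but in 94 of 240 (39.2%) and 294 of 560 (52.5%) mutant cells, and over 2% in 1 and 3 wild-type cells but in 75 (31.3%) and 169 (30.2%) mutant cells. Both limits were set after seeing the data. Mutant cells under the lower limit had a Y share of 0.0440 and 0.0441%, and those over the upper limit 0.0145 and 0.0124%, 3.04- and 3.55-fold less. The mutant cells between the limits (29.6 and 17.3%) had a Y share of 0.0698 and 0.0646%, above both. Within cluster 15, cells with a high X share were tested against those with a low one with edgeR, summed per mutant with the animal as a block. There 21 of 22 Y-linked genes fell, and of 9055 autosomal genes 922 rose and 1157 fell at an adjusted p under 0.05, with a median of -0.02 over all of them.

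**Figure D3:**
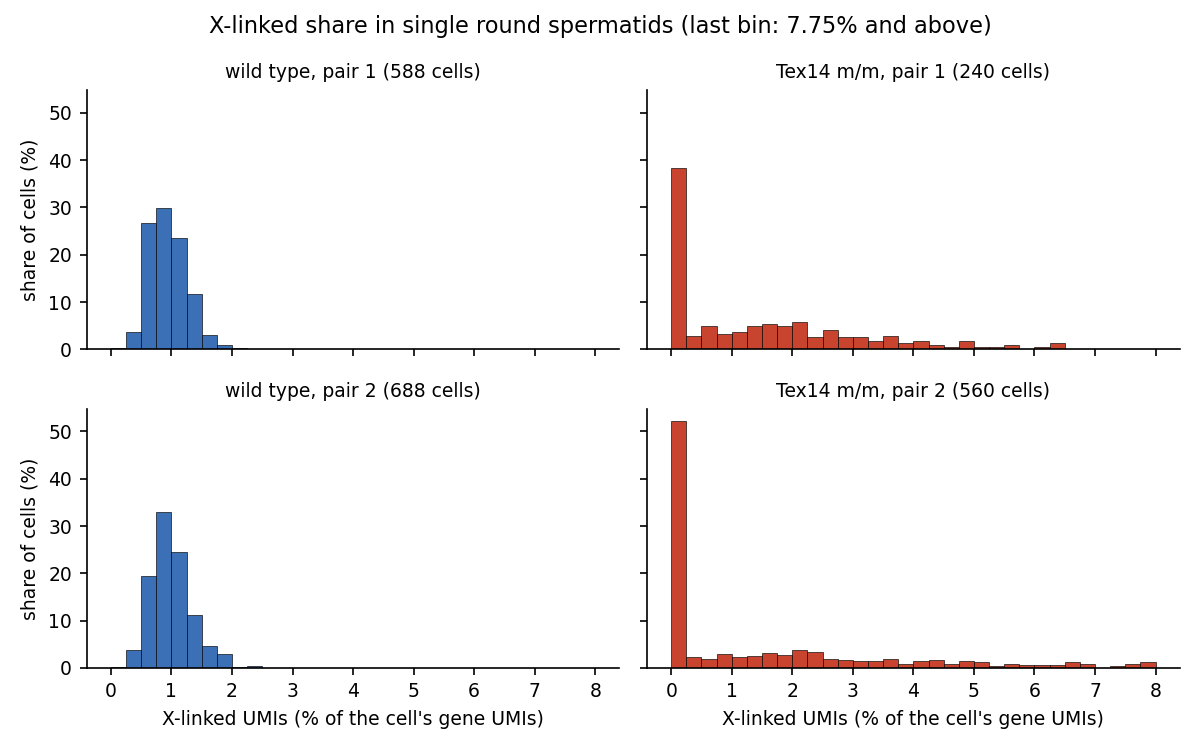
Histograms of the X-linked share of UMIs (%, horizontal axis) over round spermatids of at least 2000 UMIs, as percent of the cells of each of the 4 animals (vertical axis). Wild-type cells form a single peak with medians of 0.912 and 0.936%, and 39.2 and 52.5% of the mutant cells lie under 0.3%.

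Sertoli cells had 49 genes that rose and 553 that fell among 11016, and most of the falls named by the lists were spermatid transcripts. The gene of insulin-like growth factor binding protein 3, Igfbp3, rose from 0 and 15.1 CPM to 151 and 136 (4.58 ± 0.62, edgeR adjusted p = 0.00463). Adcy2, an adenylate cyclase gene, fell from 169 and 140 to 15.4 and 25.2 CPM (-2.97 ± 0.34, adjusted p = 0.00242). Tmem37 and the imprinted Peg3 rose from 3 UMIs each in wild types, by ratios of 15.5 (exact counting interval 5.26 to 75.2) and 12.5 (4.23 to 60.7). Timp1, an inhibitor of matrix metalloproteinases (3.57 ± 0.75), the p53 target Phlda3 (2.58 ± 0.42), Aplp1 (2.33 ± 0.39), Insc, which orients the mitotic spindle (2.26 ± 0.38), and the dopamine receptor gene Drd4 (2.20 ± 0.34) rose too. Prss58 (-3.08 ± 0.47), the prolactin receptor Prlr (-2.91 ± 0.47, but 0.11 with sex-linked genes in the clustering), Actg2 (-2.72 ± 0.45), Galntl5 (-2.65 ± 0.33), Cstdc2 (-2.61 ± 0.67) and Acte1 (-2.60 ± 0.45) fell. Without wild type 2 Cstdc2 no longer passed (-0.21), Prlr had -2.01, Acte1 -1.87 and Peg3 4.70, and for Igfbp3 and Timp1 no fold is given, since the remaining wild type had 0 CPM. Without wild type 1 Igfbp3 had 3.29, Timp1 2.28, Peg3 3.02, Prss58 -2.44 and Cstdc2 -3.56, and without mutant 1 Timp1 had 2.85 and Actg2 -3.35. Without mutant 2 the fallen genes numbered 264. DESeq2 called 21 up and 421 down, and the block 104 up and 759 down. With cells matched on UMIs 5 genes rose and 22 fell, with ambient RNA subtracted 0 and 2, without cells rich in protamine UMIs 0 and 3, and without the highest Scrublet scores 7 and 10. In the first wells alone none passed edgeR (216 higher and 385 lower at an unadjusted p under 0.05).

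All 4 spermatid lists were lower in Sertoli cells in every measured member but 2: tail genes (27, median -1.59, camera adjusted p = 4.24e-15, 11 fell and 17 adjusted over the list alone), energy metabolism (20, -1.51, adjusted p = 4.24e-15, 10 and 15), acrosome (22, -1.39, adjusted p = 2.38e-11, 5 and 15) and chromatin condensation (13, -1.99, adjusted p = 3.83e-13, 9 and 10). With an estimated correlation the lists and markers called here had an adjusted p = 0.566 to 0.645. Odf2 fell from 755 and 1027 CPM to 300 and 207 (-1.81 ± 0.33), and Akap4 (-2.12 ± 0.36), Gapdhs (-1.93 ± 0.32), Spink2 (-1.75 ± 0.35) and H1fnt (-2.46 ± 0.32) fell. Of the 16 genes of the CREM list 5 fell (7 over the list alone, -0.99, adjusted p = 0.000212), such as Spz1 (-2.01 ± 0.37, and -1.26 without wild type 2) and Tcfl5 (-1.55 ± 0.31). Elongating spermatid markers, at -1.98 (11 of 13 fell), and Leydig cell markers, at -1.77 (3 of 7 fell, adjusted p = 1.32e-05), were lower beside them. Of 17 p53 targets 14 were higher (0.65, adjusted p = 0.0108, 1 past both tests), of 7 inflammation genes 6 (0.71, adjusted p = 0.0105, 1 past both, the same Timp1) and of 23 Sertoli function genes 18 (0.24, adjusted p = 0.0194, 1 past both, Drd4). Leydig steroidogenesis passed only with the block (-0.16, adjusted p = 0.058, with the block 0.0272). Calls ended for Sertoli function without wild type 2 or mutant 1 (0.14 and 0.19), for p53 targets without wild type 1 or mutant 2 (0.33 and 0.22) and for inflammation without wild type 1 (0.25). Without mutant 1 the acrosome, tail and CREM medians were -2.27, -2.24 and -1.58. Izumo2 (-2.07 ± 0.45), Zpbp (-1.49 ± 0.35) and Tbpl1 (-1.34 ± 0.29) passed with all animals but not without mutant 2, and Izumo2 had -2.73 without mutant 1. With ambient RNA subtracted the Sertoli function median was -0.14, that of CREM -0.068, and the median over the genes of the 4 spermatid lists went from -1.54 to -0.59.

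In Leydig cells 1 gene changed among 10116: the interferon-inducible Ifi204 (ENSMUSG00000073489, chromosome 1) rose from 0 and 2.9 CPM to 106 and 118 (5.63 ± 0.50, edgeR adjusted p = 0.000594), from 3 wild-type UMIs, a ratio of 48.6 with an exact counting interval of 16.6 to 236. At an unadjusted p under 0.05 291 were higher and 531 lower. DESeq2 called 1 gene up and the block 34 up and 38 down, and without wild type 1, wild type 2, mutant 1 and mutant 2 448, 30, 97 and 29 genes passed. Spermatid lists were lower (tail -1.15, acrosome -0.86, energy -0.79, chromatin condensation -0.59, CREM -0.59, camera adjusted p = 4.89e-18, 1.24e-09, 1.42e-06, 0.000224 and 0.00311), with 18, 3, 4, 1 and 1 falls adjusted over the list alone and none over all genes. An estimated correlation gave the lists and markers called here adjusted p = 0.566 to 0.622. Of 16 heat shock and dissociation genes 9 were higher (0.20, adjusted p = 0.00712, none past either test), led by Egr1 (0.90 ± 0.28) and Fos (0.87 ± 0.28). Of 13 Sertoli function genes 10 were higher (0.38, also with a gene at 0 in wild types at its bound, adjusted p = 0.000208, 3 over the list alone), led by the transferrin gene Trf at 26.1 and 54.2 CPM against 144 and 163 (1.79 ± 0.32). All 5 mesenchymal markers were higher (1.19, adjusted p = 3.51e-08, 4 over the list alone), and Leydig steroidogenesis was not called (0.03). Inflammation passed only with the block (0.37, adjusted p = 0.0965, with the block 0.00545). Calls ended without wild type 2 for the acrosome (-0.08), CREM (-0.06), chromatin condensation (-0.35) and Sertoli function (0.46), without mutant 2 for CREM and chromatin condensation (-0.35 each) and without wild type 1 for heat shock (0.26). Without wild type 2 the tail median was -0.40, and the acrosome call ended at a tag probability of at least 0.99 (-0.14). Without the highest Scrublet scores all 5 calls ended, and the median over the genes of the 4 spermatid lists went from -0.82 to -0.067.

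Interstitial mesenchymal cells had no gene past edgeR among 5888, with 48 higher and 174 lower at an unadjusted p under 0.05, 1 up and 1 down by DESeq2 and 1 down with the block. Ifi204 had 56.4 and 38.5 CPM in wild types and 337 and 495 in mutants (3.13 ± 0.47, adjusted p = 0.384), Ccn5, a matricellular protein gene, -3.06 ± 0.50 and Flrt2 -2.13 ± 0.40. Heat shock and dissociation genes were higher (0.60, camera adjusted p = 0.00581) and chromatin condensation, tail, acrosome, energy and CREM genes lower (-1.29, -0.79, -0.67, -0.67 and -0.52, adjusted p = 5.89e-05, 1.02e-06, 0.00521, 9.65e-06 and 0.00468), none past the list alone, with adjusted p = 0.622 to 0.734 with an estimated correlation. Without wild type 1 the calls of all of these ended, with medians of 0.27, 0.24, 0.20, 0.21, -0.18 and 0.05. Without mutant 2 those of heat shock, the acrosome and CREM ended (0.077, -0.51 and -0.0017), and without mutant 1 the tail median was -1.70. Without the highest Scrublet scores the 5 spermatid and CREM calls ended (4 spermatid lists together -0.79 and then -0.22).

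Macrophages had 8 genes that rose and 1 that fell among 3551. Spp1 rose from 101 and 107 CPM to 2478 and 845 (4.0 ± 0.61, edgeR adjusted p = 0.0311). Ptgds, a prostaglandin synthase gene, rose by 3.95 ± 0.65 and the glutathione transferase gene Gstm2 by 3.17. Prlr, with no wild-type UMI, reached 133 and 152 CPM, at least 8.17-fold higher against a floor of 3 UMIs over the group. Few wild-type UMIs also lay behind Lcn2 (ratio 34.3, exact interval 11.7 to 167) and Aldh1a1 (48.9, 8.70 to 1939). Others were Auts2 (23.9, 6.54 to 198) and Hsd3b6 (19.6, 5.36 to 163). Lcn2, Hsd3b6 and Ptgds also marked Leydig cluster 9, and carried-over Leydig RNA was not tested. Nudt16l2 fell by 2.46 ± 0.43 (adjusted p = 0.0490). None of the 9 passed without wild type 2, and Hsd3b6, Prlr and Nudt16l2 did not without mutant 1. Ptgds had 5.72 without wild type 1 and 2.91 without wild type 2, and Spp1 4.59 without mutant 2. DESeq2 called 11 genes, all up, and the block 27 up and 26 down. No gene passed edgeR with ambient RNA subtracted (79 higher and 45 lower at an unadjusted p under 0.05), cells matched on UMIs (25 and 48), cluster 8 alone (33 and 25) or the first wells alone (13 and 17). The wild-type cells lay mostly in cluster 8 (33 of 44 and 39 of 63), as did those of mutant 2 (65 of 89). Mutant 1 had 170 of 330 in cluster 16 and 114 in cluster 8. Spp1 marked cluster 14, which held 46 and 2 mutant cells and no wild-type cell, so its rise may follow cluster make-up. Spermatid lists were lower (chromatin condensation -1.0, tail -0.94, acrosome -0.84, energy -0.75, CREM -0.59, camera adjusted p = 0.000122, 3.64e-05, 0.00468, 1.46e-05 and 0.00513, no member past either test). An estimated correlation gave the lists called here adjusted p = 0.598. In these cells 6 Sertoli function genes were higher (0.65, adjusted p = 0.0007, 1 over the list alone), and 3 meiotic initiation genes had 1.31 (adjusted p = 0.000208, 1 past the test and 2 over the list alone), of which Aldh1a1 makes retinoic acid. Calls ended for chromatin condensation and Sertoli function without wild type 2 (-0.14 and 0.42) and for the acrosome without wild type 1 or mutant 2 (-0.65 each). Without the highest Scrublet scores those of the spermatid and CREM lists ended (4 spermatid lists together -0.87 and then -0.33).

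Over all classes 66 of 185 tests of gene lists were called by camera, 65 of them also with the block, and 0 held with an estimated correlation after adjustment (9 at an unadjusted p). Of 90 marker tests 38 and of 19 sex-linked tests 9 were called, of which 0 held likewise (3 and 4 at an unadjusted p). With 4 animals these failures decide nothing. Lists of intercellular bridges and cytokinesis, the interferon response, the unfolded protein response and Leydig steroidogenesis were called in no class. With the pair as a block the bridge list passed in mesenchymal cells (median -0.40, camera adjusted p = 0.0778, with the block 0.0336). In no called test did the median and the direction of the test differ in sign.

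**Figure D4:**
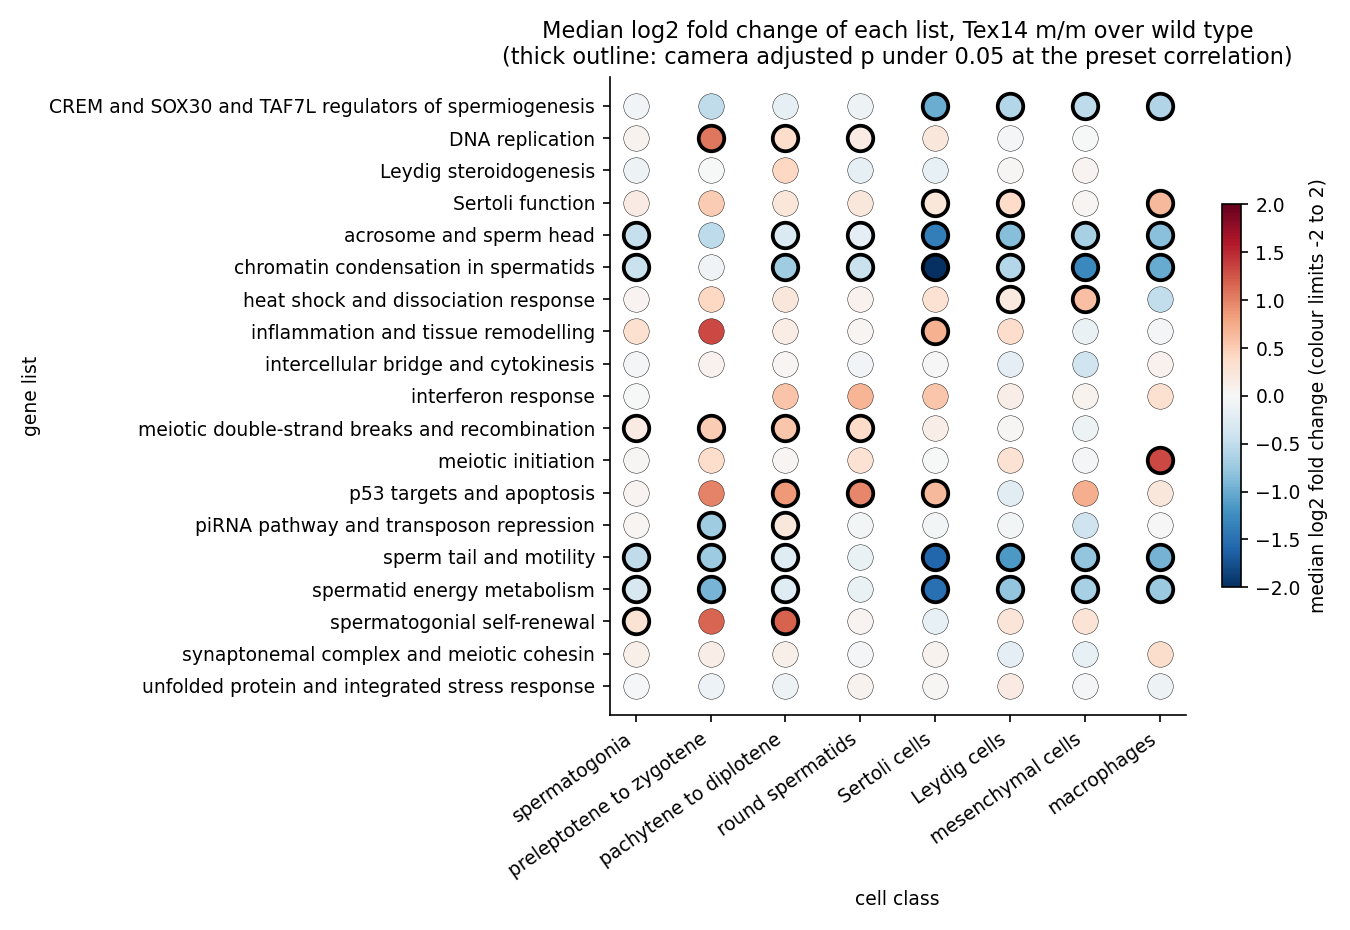
Median log2 fold change, mutant over wild type (colour), of the gene lists (vertical axis) in 8 of the tested classes (horizontal axis), with a thick outline where camera called the list at the preset correlation. Chromatin condensation has a median of -1.99 in Sertoli cells.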

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

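Among the tests in this part, the comparison with the nearest wild-type cells and that of MMERVK10C in spermatogonia and Sertoli cells were chosen only after the result was seen.

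The Y-linked share of UMIs was higher in both mutants than in their wild-type partners in preleptotene to zygotene spermatocytes, and lower in both in pachytene to diplotene spermatocytes and in round spermatids. The log2 changes of the earlier class exceeded those of the later classes by 2.38 and 3.06 on average over the pairs, and these differences were not tested. The share of intracisternal A particle (IAP) transcripts went the other way in the same early class. It was 0.0671 and 0.0795% in wild types and 0.0301 and 0.0471% in mutants there. It was higher in both mutants than in their partners in spermatogonia and in pachytene to diplotene spermatocytes. The log2 changes of these classes exceeded that of the early one by 1.15 and 1.34, untested. B1 elements, a family of short interspersed repeats, had lower shares in both mutant animals in spermatogonia and higher shares in the later classes. The untested differences of the log2 changes to spermatogonia were 0.72 for preleptotene to zygotene spermatocytes, 0.52 for pachytene to diplotene spermatocytes and 0.46 for round spermatids.

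Cells with no tag call were used in no comparison. Of those with at least 1000 UMIs, 31.0 and 26.6% in the wells of pair 1 and 11.6 and 19.8% in the wells of pair 2 had over 2% of their UMIs from protamine and transition protein genes. Among cells tagged as wild type the percentages were 59.5, 60.0, 38.6 and 49.0 in the same order, and among cells tagged as mutant 1.75, 1.8, 0.432 and 2.83.

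Mutant cells of cluster 4, within the preleptotene to zygotene class, had 4.88 and 5.94 times the X share of the wild-type cells of that cluster, with more MMERVK10C and young LINE-1 UMIs. A difference in stage within the cluster may explain the first, since against the nearest wild-type cells the X fold was at most 1.07. For young LINE-1 stage and genotype cannot be told apart: a wild-type germ cell cluster held up to 2.17 times the mutant share, but against the nearest wild-type cells the folds stayed at 1.47 and 1.48 (1.74 and 1.97 in the whole cluster). Nor can they for MMERVK10C, where a wild-type cluster of 26 cells in pair 1 reached 1.08 times the mutant share, that of 23 cells in pair 2 had 0.179% against 0.401%, and the nearest-cell folds were 2.49 and 5.63. In cluster 5 these folds were 2.14 and 1.72 for MMERVK10C, 1.08 and 0.98 for young LINE-1 and 1.01 and 0.98 for X. A copy difference inherited beside Tex14 or an effect of the mutant allele stays open for MMERVK10C too, neither tested alone. Its log2 change was 0.24 in spermatogonia and 2.41 in cluster 4, but 1.56 ± 0.37 in Sertoli cells.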

How the results depend on the processing

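Chosen only after the data were seen were the tests in single clusters, with sex-linked genes in the clustering, on cells matched on UMIs, without cells rich in protamine UMIs, without the highest Scrublet scores and the tests of repeats. With 2 animals per genotype, leaving out 1 leaves a lone animal, which is assumed to vary like the other genotype. Depth limits the rare classes, and a tag probability of at least 0.99 assigned only 8.74, 4.48, 18.5 and 9.55% of the cells of the 4 wells to wild types and 22.8, 19.3, 5.98 and 0.988% to mutants. Ambient subtraction removes spermatid transcripts by construction. Clusters from wild-type cells alone held no undifferentiated spermatogonia, endothelial or lymphoid cells. For the changes below the cause was not tested.

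With the pair as a replicate block 78 of 78 called genes named and 74 of 75 called lists kept their call. Besides the lists, counts and repeats given with their classes above, and the counts below, these lists passed only with the block: in mesenchymal cells Leydig markers (median -1.42, adjusted p = 0.0768 and with the block 0.0118), heat shock in macrophages (-0.49, 0.0782 and 0.0257), and peritubular myoid markers in Leydig cells (0.65, 0.0540 and 0.0326). In differentiating spermatogonia they were piRNA (0.04, 0.107 and 0.0427), synaptonemal complex (0.10, 0.115 and 0.0299) and X-linked genes (0.06, 0.0647 and 0.0480). Among repeats the block also called B2_Mm1a and IAPLTR2_Mm in undifferentiated spermatogonia (0.55 and 2.9, adjusted p = 0.0241 each) and BC1_Mm in macrophages (1.43, adjusted p = 0.0233). As groups it called B2 elements in undifferentiated spermatogonia (0.41), preleptotene to zygotene (0.95) and pachytene to diplotene spermatocytes (0.39), IAP in undifferentiated (0.37) and B1 in differentiating spermatogonia (-0.27), with adjusted p = 1.55e-05 to 0.0393. Of the called genes named, DESeq2 kept 73 of 78, its size factors 78, Leiden resolution 2 70 of 72, wild-type clusters 70 of 72 and the second wells 70 of 76. Fewer held with the first wells (33 of 72), ambient RNA subtracted (36 of 62), matched UMIs (43 of 70), a tag probability of at least 0.99 (34 of 65) and Leiden resolution 0.5 (36 of 71). Of the called lists, size factors kept 75 of 75, Scrublet removal 74, no count filter 70, matched UMIs 50 of 71, ambient subtraction 42 of 70 and removal of the highest Scrublet scores 40 of 67.

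Changed genes in preleptotene to zygotene spermatocytes numbered 3195. There were 2109 with DESeq2, 5667 with the replicate block, 5032 at Leiden resolution 2, 0 at 0.5, 1570 with matched UMIs, 529 in cluster 4, 1152 in the first wells and 1725 at a tag probability of 0.99. In pachytene to diplotene spermatocytes there were 0, against 42 with DESeq2, 327 with no count filter, 2878 with the block, 1 without the highest Scrublet scores and 0 to 739 with 1 animal left out. In round spermatids there was 1. DESeq2 gave 74, no filter 325, the block 789, cluster 18 203, and Leiden resolutions 0.5 and 2 and clustering with sex-linked genes 4 each. It was 0 with size factors, matched UMIs, cluster 15, either well alone, stricter cells, a tag probability of 0.99, wild-type clusters and both Scrublet removals, and 66 to 158 with 1 animal left out. Spermatogonia had 0, against 1 with DESeq2, 8 with no filter, 82 with the block and 0 to 10 with 1 animal left out. The number of changed genes in somatic classes was 612. Ambient subtraction left 5, matched UMIs 28, the first wells 0 (the second 674), removal of cells rich in protamine UMIs 13 and of the highest Scrublet scores 19. No filter gave 1030, the block 989, wild-type clusters 1136 and 1 animal left out 382 to 1179.

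Changed repeats in preleptotene to zygotene spermatocytes numbered 10. They were 0 and 78 at Leiden resolutions 0.5 and 2, 26 in cluster 4, 37 with the block. They were 6 with sex-linked genes in the clustering, 5 at a tag probability of 0.99, 4 in the second wells, 3 with wild-type clusters and without cells rich in protamine UMIs, 1 with matched UMIs and in the first wells, and 7 to 23 with 1 animal left out. The block gave 15 in pachytene to diplotene spermatocytes, 2 in spermatogonia and 1 in round spermatids, where there were 0, and leaving out 1 animal gave 0 to 2 and 0 to 3 in the first and second of these. List tests called fell from 66 to 43 with matched UMIs and 35 without the highest Scrublet scores.

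The change of Tex14 in preleptotene to zygotene spermatocytes was 0.43 with and without the replicate block, -0.37 and 0.91 at Leiden resolutions 0.5 and 2 and 0.80 in the second wells. The log2 ratio of median UMIs there was 0.02, but -0.49 in cluster 4, -0.31 in the second wells and -0.79 with stricter cells, and that of genes per cell 0.12, but -0.29, -0.088 and -0.48. For pachytene to diplotene spermatocytes cluster 13 turned the ratios of 0.78 and 0.42 to -1.06 and -0.57, and for macrophages cluster 8 turned 0.23 and 0.19 to -0.12 and -0.13. The log2 ratio of the X share was 0.63 in pachytene to diplotene spermatocytes but -0.25 in cluster 17, and 0.74 in round spermatids but -0.58 as a median over cells. For the Y share it was -0.03 in Leydig cells but 0.10 as a mean over cells and 0.18 in the second wells. It was 0.11 in Sertoli cells but -0.18 as a mean over cells, and -0.07 in macrophages but 0.19 in the second wells and 0.083 with wild-type clusters. That of the endothelial share was 0.10, but -0.71 in the second wells and -0.065 without the highest Scrublet scores.

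Leiden resolution 0.5 reversed in preleptotene to zygotene spermatocytes Cadps2 (-0.35), Gml (0.28), Gml2 (0.24), Gstt2 (0.19), Lypd11 (0.19), H2afx (0.36), IAPLTR3 (0.42) and the piRNA list (0.053). Sex-linked genes in the clustering reversed Prlr in Sertoli cells (0.11). Ambient subtraction reversed acrosome genes in spermatogonia (0.43) and differentiating spermatogonia (0.45), energy metabolism in spermatogonia (0.16), differentiating (0.15) and undifferentiated spermatogonia (0.043). It reversed chromatin condensation in pachytene to diplotene spermatocytes (0.23), the CREM list in mesenchymal cells (0.17), and in Sertoli cells Sertoli function (-0.14) and X-linked genes (-0.074). Wild-type clusters reversed acrosome genes in pachytene to diplotene spermatocytes (0.038), a tag probability of 0.99 the Y-linked genes there (0.42) and cluster 17 the X-linked genes there (-0.11). The direction of the test turned while the median kept its sign with ambient subtraction for the CREM list in Sertoli cells (-0.068) and macrophages (-0.037), X-linked genes in mesenchymal cells (0.039) and chromatin condensation in differentiating spermatogonia (-0.0068). The same held in cluster 8 for Sertoli function in macrophages (0.047), at a tag probability of 0.99 for the acrosome in Leydig cells (-0.14) and with wild-type clusters for recombination in pachytene to diplotene spermatocytes (0.013). Ambient subtraction removed 100% of the UMIs of wild type 1 in mesenchymal cells, so its values there, those of the CREM list and X-linked genes included, say nothing about stability.

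With each animal left out in turn, the log2 ratio of median UMIs ranged from -0.26 to 0.14 in Leydig cells, -0.36 to 0.22 in mesenchymal cells, -0.13 to 0.53 in macrophages, -0.63 to 1.47 in pachytene to diplotene and -0.15 to 0.17 in preleptotene to zygotene spermatocytes. Genes per cell ranged from -0.17 to 0.085 in Leydig cells, -0.28 to 0.12 in mesenchymal cells, -0.15 to 0.47 in macrophages and -0.40 to 0.94 in pachytene to diplotene spermatocytes. The Y share ranged from -0.26 to 0.24 in Leydig cells, -0.043 to 0.24 in Sertoli cells, -0.16 to 0.54 in mesenchymal cells, -0.35 to 0.26 in macrophages and -0.12 to 0.21 in spermatogonia, and the endothelial share from -0.56 to 1.33. The acrosome median ranged from -1.31 to 0.21 in mesenchymal cells and -1.33 to 0.60 in undifferentiated spermatogonia.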

Other observations

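Of the tests in this part, those on cells of a type with a high X share, on silenced spermatocytes, on shallow cells, on transcripts that stay with their chromosome, on low cells of other classes, the comparisons within clusters 15 and 18, and those on cells matched on UMIs, without cells rich in protamine UMIs and without the highest Scrublet scores were chosen only after the result was seen.

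Few mutant cells of cluster 18 had a low X share (1 of 33 and 2 of 95), so its X-linked rise does not cover low cells. Dach2, a transcription factor gene, rose there by log2 4.56 ± 0.45. The testis genes Btbd35f17 and Btbd35f27 rose by 3.64 ± 0.54 and 3.57 ± 0.34, and Ssxb1 by 3.30 ± 0.49 (edgeR, adjusted p = 0.00670 to 0.0166).

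Many mutant round spermatids had a low X share, and the others spread up to a high share with no gap at the upper limit. Among wild types 1 of 588 and 2 of 688 cells had a low and 1 and 3 a high share. The tables argue against shallow cells as the cause, since at least 41.0% of the mutant cells with 10000 UMIs or more lay under the lower limit, and within cluster 15 against silenced spermatocytes as the low cells, whose Y share was at least 2.62 times that of wild-type pachytene to diplotene cells and 2.15 times that of low wild-type cells in any spermatocyte cluster. Within cluster 15 a type with a high X share is argued against too, since over X-linked genes of the high cells every tested wild-type class that reaches the upper limit correlated worse than round spermatids by at least 0.488. Other cell types or doublets stay open, in cluster 15 too: over the same genes wild-type pachytene to diplotene cells came within 0.0812 of round spermatids. In cluster 23 low mutant cells (17 and 115) had a Y share of 0.0213 and 0.0309%. Low wild-type cells of spermatocyte cluster 13 had 0.0229 and 0.0202%. Without the highest Scrublet scores 40.3 and 54.4% of mutant cells were still low and 31.5 and 29.7% high. The hypothesis that sex-linked transcripts stay in the spermatid that carries the chromosome stays open: within cluster 15 the Y share of the low cells (0.0491 and 0.0540%) was at least 6.97 times that of the high cells, but below that of the mutant cells between the limits (0.0583 and 0.0581%) and of wild-type cells (0.0813 and 0.0891%).

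Spermatid transcripts were lower in mutant Sertoli cells, with a median of -1.54 over 82 genes (quartiles -1.81 and -1.15), of which 35 passed. Free RNA of the well that weighs more in the shallower wild-type cells stays open. Cells matched on UMIs had a median of -1.30 (quartiles -1.50 and -0.87, 4 of 59 genes passed), which met the limit set against this explanation. However, the median cell of the 4 wells held 22, 19, 8.5 and 20 protamine and transition protein UMIs in wild types. It held 18, 17, 10 and 19 in mutants, whose cells were deeper, while the means were 1.08 to 6.77 times higher in wild types. Subtraction of ambient RNA takes these UMIs as free RNA by construction and decides nothing. Spermatid RNA in a few wild-type cells, as doublets or material taken up, could account for part: without cells rich in protamine UMIs the median was -1.10 over 81 genes and without the highest Scrublet scores -0.91 over 71. The first lies between the limits set for and against it, so it cannot be told apart from a broader difference between the genotypes, such as the few elongating spermatids of mutants, which was not tested on its own.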
